A study of Canis lupus familiaris with 4 samples.

How the data were processed

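Gene expression was compared in MDCK cells, a canine kidney epithelial line, transfected with E2-2 (the class I basic helix-loop-helix factor encoded by TCF4). The transfectants E22A and E22B were each hybridised against RNA of the MDCK-CMV control on a spotted cDNA array of clones printed in duplicate, per the labels. There were 4 arrays, 2 per transfectant, described in the series' design text as a reciprocal exchange of Cy3 and Cy5. The design text gives a dye swap per transfectant, so the arrays of a transfectant were treated as technical repeats and each transfectant counted as 1 biological replicate. E22A and E22B were taken as isoforms A and B of E2-2, so neither repeats the other. The control RNA lay on every array.

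The values are log2 ratios of the dyes of each array, as deposited by the authors. The logarithm's base is an assumption from convention and no header or label gives it, so every fold below rests on it. The deposited medians of the 4 arrays were 0.00294, 0.00186, -0.000946 and -0.00991, so the columns had been centred. Image analysis, background correction, spot filter, normalisation and the dye in the numerator are not given in the sources used here, and scanner intensities were not used here. Signal over background could therefore not be weighed, and the number of arrays limits the precision.

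The table held 27648 spots from 13824 clones. The platform annotation gave 1 gene symbol for 8744 clones, several for 327 and none for 4753. It named 6043 different genes, of which 5506 symbols also occur in the dog gene table. The array was made for human genes and read with canine RNA, so a gene's ratio also depends on hybridisation across species. Duplicate spots were averaged. Each array was centred on its median. Clones with a value on all 4 arrays (10268) were kept and averaged by gene where they had 1 symbol, and clones with no symbol or several stayed as their own feature. This gave 8657 features, 4892 with a gene symbol, and 1207 genes rested on more than 1 clone. Among 43 of these genes that had a clone at 2-fold or more in E22B, 18 had clones on both sides of 0.

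Orientation followed a rule set before the data were examined. For E22B, titles and channel labels name the same dyes. Its arrays correlated at r = -0.407 across features as deposited, so the values were read as plain dye ratios and array 1 was turned. For E22A array 1 the title names Cy5 and the channel labels put E22A in Cy3. That title also spells the transfectant EE2A, and the array was assigned to E22A because the protocol text of its first channel names E22A cells. Turned by the titles, the E22A arrays correlated at r = -0.371, below the limit of -0.3, so E22A has no settled direction. The title reading is the main one, as fixed beforehand, and the channel-label reading is given beside it. A pair of further readings was tried after the data were seen. One took the values as channel 2 over channel 1. The other took the E22A arrays together with the sign turned. That makes 4 readings in all. The channel-label reading conflicts with the design text, which describes reciprocal labelling for each transfectant.

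Positive values are on the side on which CDH1 lies in E22B, called the E-cadherin side. If Cy5 is the numerator this side means higher in the transfectant, and if Cy3 is, lower. The first choice is the usual one and would place E-cadherin higher in the transfectants, which opposes the repression of E-cadherin by E2-2 known for these cells.

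The pooled comparison tested the mean log2 ratios of E22A and E22B, each over its arrays, against 0 with limma 3.58.1 in R 4.3.3 (lmFit, eBayes, Benjamini-Hochberg adjustment, threshold 0.05). It takes the isoforms as replicates of E2-2 transfection, so a difference between them counts as spread and neither is replicated. The test leaves out the control's own spread. A mean over opposite dyes cancels a gene's dye effect. By the channel labels E22A is in Cy3 on both arrays, so its mean keeps that effect in every result of that reading. A single transfectant has no replicate and no test, so features were counted at 2-fold or more, on the same side, on both of its arrays. E22A was set against E22B by counting differences of 1 log2 unit or more between these means, with no overlap between the arrays. The 20 gene lists, fixed before the data were examined, were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. At the preset correlation the p-value rests on the spread over genes, not over samples. The other versions have 1 residual degree of freedom here, so they could hardly call any list, and a call lost with them says little. For each transfectant a list's median was placed among 10000 random lists of its size, not matched on expression. Counts shared by the transfectants were set beside 100 simulations per reading of unchanged groups with a common control. Their spread was taken from the measured values, averaged over the transfectants, and so includes any effects. By the titles the E22A arrays run against each other, which lowers that average. Intervals of correlations come from 1000 resamplings of features. Features are not independent replicates.

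Genes were named by a rule set beforehand. It took 14 genes of the E-box and epithelial-mesenchymal system where measured, and genes passing the pooled test or, failing that, at 2-fold or more on all 4 arrays (up to 12 per side). It also took up to 8 per side for each transfectant's size rule, up to 6 per side for E22A against E22B, and up to 4 members of each list on the same side of all 4 arrays. Genes outside it are said to be chosen afterwards.

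The scripts were tested on simulated data with 8657 features, 200 of them changed. The pooled test recovered 0% of changes of 1 log2 unit, 88.5% at 2 and 99% at 4, with 0, 6 and 17 false calls. For E22B the size rule recovered 21.5%, 98% and 99.5%, with 24, 28 and 23 false counts. A list shifted by 0.5 was called and 0 of 19 other lists were. The simulated genes were independent, so this does not bound false calls of lists whose genes are correlated. In an early version the simulated spreads were too narrow, and they were redrawn from limma's fitted prior before the percentages above were computed. No measured value depends on them. Alternatives covered centring, scaling, clone averaging, missing values, thresholds, tests, left-out arrays, unreliable features and the readings above. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.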

Results

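The data are 4 arrays with 2 dyes each of MDCK cells, a line of canine kidney epithelium, carrying E22A or E22B, the E2-2 transfectants, each read against MDCK-CMV control cells. The series addresses how basic helix-loop-helix factors, E2-2 among them, regulate E-cadherin and the epithelial-mesenchymal transition. Spots with a value numbered 23006 and 22581 on the E22A arrays and 23136 and 22360 on the E22B arrays. Duplicate spots of a clone correlated at 0.981, 0.966, 0.901 and 0.965. Each transfectant is 1 biological sample, and every SD below is over its 2 arrays, so it measures technical spread.

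In E22B, CDH1 (E-cadherin, the main adhesion molecule of epithelial junctions) and FN1 (fibronectin, a matrix protein of mesenchymal cells) lay on opposite sides of the control, at 0.93 ± 0.20 and -1.72 ± 0.51 (log2, SD, n = 2 arrays). The CDH1 value rests on the clone measured on all 4 arrays. Another CDH1 clone, without a value on E22A array 2, gave 2.31 ± 1.97 in E22B, from -3.71 and 0.92 as deposited. Which side is higher in the transfectant is not settled, because the dye in the numerator is not stated. The usual Cy5 over Cy3 would place CDH1 higher in E22B, which opposes the study's known direction of E-cadherin repression. With CDH1 lay FOS, an immediate early transcription factor, at 3.21 ± 0.14, a 9.23-fold ratio. TFF1, a secreted trefoil peptide, stood at 2.57 ± 0.29, and KLF4, an epithelial transcription factor, at 2.44 ± 0.57. LRATD2 stood at 1.81 ± 0.98, FGB, the fibrinogen beta chain, at 1.65 ± 0.87 and CDC6, a replication licensing factor, at 1.57 ± 0.32.

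With FN1 lay TMSB4X, an actin-binding thymosin, at -2.01 ± 0.91, and TMSB4Y at -1.45 ± 0.39, a near-identical relative that hybridisation was not shown to tell apart. PPP1R14B, a phosphatase inhibitor, stood at -1.70 ± 0.53 and ESM1, an endothelial proteoglycan, at -1.48 ± 0.57. In all, 55 of 8657 features were at 2-fold or more on both E22B arrays. Of these, 45 were on the E-cadherin side and 10 on the other, and 32 had a gene symbol. A further 10 were at 2-fold on both arrays but on opposite sides after turning, as dye bias gives. Simulated unchanged groups met the rule in 0.25 (titles) and 7.74 (channel labels) features with 1 spread for all features. With each feature's own observed size they met it in 32.4 and 71.5. The simulated spread was averaged over both transfectants, although E22B has the same values in both readings. By the titles the opposed E22A arrays lower the part shared by the arrays of a transfectant. The 0.25 and 32.4 are therefore no chance counts for E22B. Both spreads include any effects, so the number of the 55 that unchanged groups would give is not settled. DYRK2 (4.36 ± 4.04) and TOR1AIP1 (2.96 ± 2.72) met the rule only with very unequal arrays. E22B has no biological replicate, so no test was made.

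The transfected gene itself, TCF4, stood at -0.09 ± 0.25 in E22B, and its deposited ratios were 0.27 and 0.08 on arrays of opposite dye, so it did not turn with the dye. Whether its 2 clones cover the transfected sequence is not given in the sources used here, and TCF4 therefore checks neither the labels nor the direction. TCF3, the gene of E47, stood at -0.40 ± 0.05. The inhibitors of these factors stood at -0.32 ± 0.13 (ID1), -0.37 ± 0.34 (ID2) and -0.70 ± 0.30 (ID3), all on the FN1 side. CDH2, N-cadherin, was at -0.25 ± 0.79 and ZEB1, an E-cadherin repressor, at 0.02 ± 0.18. SNAI1 and TWIST1 lacked a value on E22A array 2 only, and their clones stood at 0.33 ± 0.16 and -0.04 ± 0.44 in E22B. VIM and SNAI2 had no value on any array, and ZEB2 had no clone in the annotation used.

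**Figure D1:**
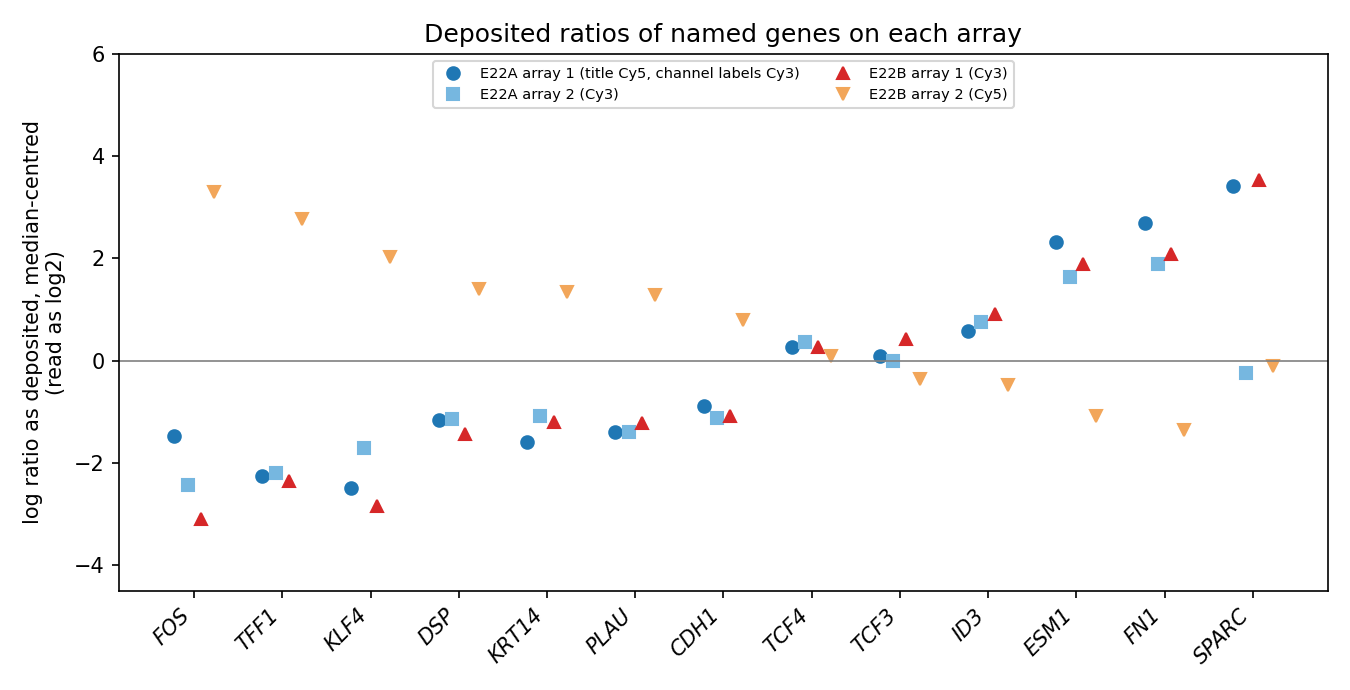
Deposited log ratios (read as log2, median-centred, sign not turned) of 13 genes, with 1 point per array. FOS to CDH1 lie below 0 on 3 arrays and above 0 on E22B array 2, and ESM1 and FN1 lie the other way, while SPARC stands at 3.43 and 3.54 on the first arrays and at -0.25 and -0.11 on the second.

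In E22A, CDH1, FN1, TFF1 and KLF4 also stood far from 0 on both arrays, but the direction depends on which label is believed. Other genes of E22B did not, such as FGB (0.18 and 0.17 as deposited), PPP1R14B (-0.72 and -0.14) and TMSB4X (2.81 and 0.22). As deposited, CDH1 was at -0.90 and -1.13, and FN1 at 2.68 and 1.89. The channel labels give CDH1 1.01 ± 0.16, FN1 -2.28 ± 0.56, TFF1 2.22 ± 0.04, HERPUD1 (a protein of endoplasmic reticulum stress) 2.14 ± 0.36 and KLF4 2.09 ± 0.55. The titles cancel them, giving CDH1 0.11 ± 1.43 and FN1 0.40 ± 3.23. By the titles only EGR1 (2.30 ± 1.33) and RGS2 (-1.53 ± 0.21) were at 2-fold on the same side of both arrays, 2 features, against 33 on opposite sides. On the E22B arrays EGR1 stood at 1.00 and 3.54 and RGS2 at -2.37 and -1.05 as deposited. There both were at 2-fold on opposite sides after turning, as dye bias gives. By the channel labels there were 33 features, 22 on the E-cadherin side and 11 on the other (31 and 9 with the arrays scaled alike), against 2 on opposite sides. In that reading E22A is in Cy3 on both arrays, so a gene's dye bias falls on the same side of both. The 33 against 2 therefore cannot part an effect from dye bias, and the SDs of E22A in that reading leave dye bias out. Also 2-fold in that reading were FOS (1.95 ± 0.68), TIMP3, a metalloproteinase inhibitor (1.52 ± 0.06), PLAU, the urokinase activator (1.39 ± 0.01), DPP4 (1.38 ± 0.50) and KRT14, a basal keratin (1.34 ± 0.36). On the other side were ESM1 (-1.97 ± 0.49), POSTN, periostin (-1.45 ± 0.35), STC1 (-1.32 ± 0.03), RCN2 (-1.23 ± 0.30) and C17orf58 (-1.10 ± 0.09). With the sign of the pair turned, each of these values changes sign and the count stays 33. TCF4 stood at -0.32 ± 0.07 by the channel labels and at -0.05 ± 0.45 by the titles.

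Pooling the transfectants gave 0 features at an adjusted p under 0.05 (limma) in the title reading, with 283 at an unadjusted p under 0.05 where chance gives 433 and a smallest adjusted p of 0.952. The channel-label reading gave 1 feature, a clone without a gene symbol on the E-cadherin side (adjusted p = 0.0422), with 1158 at an unadjusted p under 0.05. The count became 0 without median centring, with incomplete features, or without E22A array 1, E22A array 2 or E22B array 1, and 31 without E22B array 2. No named gene passed in either reading. In the channel-label reading KLF4 and TFF1 each had an adjusted p of 0.0506, and CDH1, FN1, DSP, KRT14 and PLAU each 0.0680. By size alone, 14 features were at 2-fold or more on all 4 arrays in the channel-label reading and 0 in the title reading. The 10 with a symbol were TFF1, KLF4, FOS, ASNS, DSP (desmoplakin, of desmosomes), KRT14, DPP4 and PLAU on the E-cadherin side, and FN1 and ESM1 on the other. DSP stood at 1.42 ± 0.02 in E22B and 1.16 ± 0.02 in E22A, and ASNS, asparagine synthetase, at 1.46 ± 0.44 and 1.31 ± 0.33. Both values share the control RNA and rest on 2 transfectants, and the E22A value keeps any dye effect of the gene. With the sign of the E22A pair turned, the pooled test called 0 features.

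Across features E22A and E22B correlated at r = -0.0578 (Spearman's rho -0.0532) by the titles and at r = 0.355 (rho 0.312) by the channel labels. Unchanged groups that share a control gave a simulated r of 0.0763 and 0.281 at the measured noise, and 0.5 without noise. The spread used at the measured noise came from the measured values, averaged over both transfectants. By the titles the E22A arrays run against each other, which lowers that average below E22B's own. The simulated r of 0.0763 and covariance of 0.00621 by the titles therefore cannot serve as values of unchanged groups. The spread also includes any effects and, by the channel labels, any dye effect of E22A, so the comparison cannot part effects from the shared control. The covariance was -0.00411 against a simulated 0.00621 by the titles, and 0.0373 against 0.0299 by the channel labels. In the channel-label reading 11 features on the E-cadherin side and 3 on the other met the size rule in both transfectants, where independent lists give 0.114 and 0.0127, and 2 met it on opposite sides. Simulated unchanged groups that share the control gave 0.01, 0 and 0 with 1 spread for all features, and 5.38, 5.6 and 2.38 with each feature's own observed size. Both spreads include any effects. The control has 1 sample and could not be split, so part of the excess may come from it. Of the 55 features of E22B, 40 were on its side on both E22A arrays by the channel labels (72.7%) and 4 by the titles (7.27%). The same simulations gave 67.3% and 51.1% by the channel labels, and 36% and 29.7% by the titles, the 36% from 0.25 features per simulation. The title percentages rest on the same lowered spread and decide nothing.

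**Figure D2:**
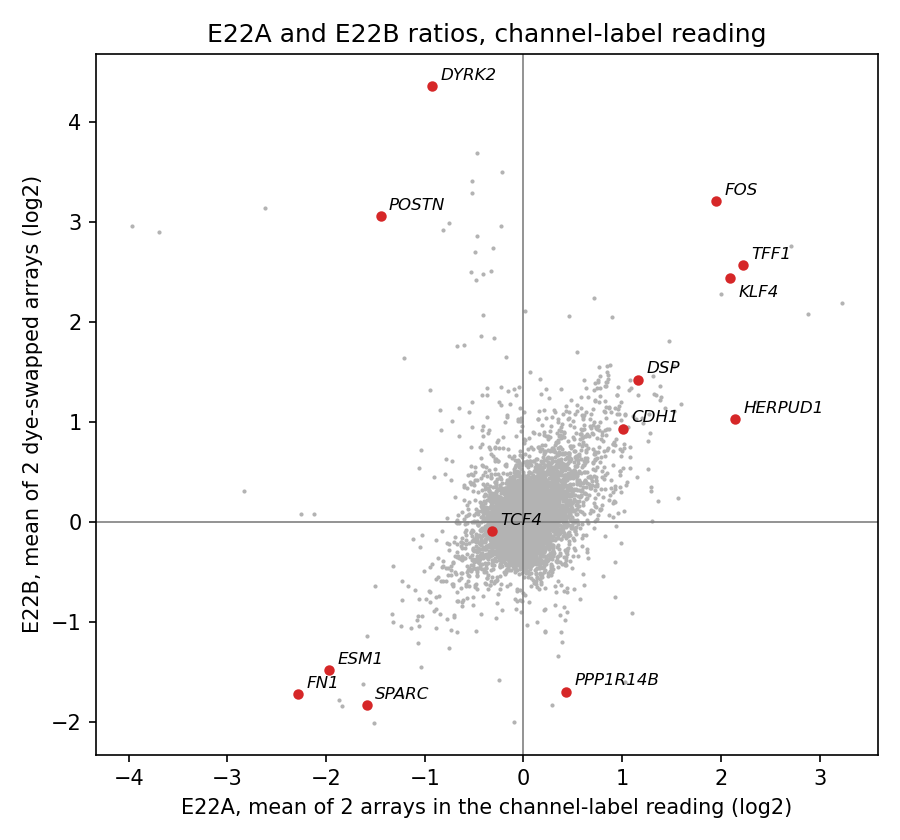
Each point is 1 of 8657 features, with the E22A log2 ratio in the channel-label reading on the horizontal axis and the dye-averaged E22B log2 ratio on the vertical axis, and named genes in red. FOS, TFF1, KLF4, DSP and CDH1 lie at upper right, FN1 and ESM1 at lower left, and r is 0.355, or -0.355 if the sign of E22A is turned.

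E22A against E22B asks whether the transfectants differ, and with 1 sample each no test between biological samples was made. By the titles 146 features differed by 1 or more without overlap, 34 higher in the E22A value and 112 lower, and by the channel labels 130, 36 and 94. The channel-label differences keep any dye effect of E22A. By the channel labels PPP1R14B stood 2.12 above in E22A, ALG8 2.01 (1.29 without E22B array 2), KYNU (kynureninase) 1.59, KIAA1958 1.34, KISS1R 1.32 and VPS28 1.20. At the other end were DYRK2 (-5.29), POSTN (-4.51), TENM3-AS1 (-3.93), USP45 (-3.73), BMPR1B (-3.71) and TOR1AIP1 (-3.19), each with its largest value on E22B array 2. By the titles SPARC (3.66), TMSB4X (3.30), SCN9A (2.27), GNG11 (2.21), TMSB4Y (2.15) and GABBR2 (1.88) stood above, and KLF4 (-2.83), FOS (-2.73) and TFF1 (-2.59) were among those below. SPARC, SCN9A, GNG11 and GABBR2 were under 0.5 in size on the second array of each transfectant.

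Genes of the heat shock and unfolded protein response, 16 measured, shifted to the E-cadherin side in both readings (camera adjusted p = 3.25e-09 by the titles, 1.32e-06 by the channel labels). The call was lost with an estimated correlation (adjusted p = 0.921 and 0.869). That version and fry have 1 residual degree of freedom here and could hardly call any list, so their results below decide nothing. As deposited, the list's medians were -0.18 and -0.14 on the first arrays and -0.75 and 0.73 on the second, farther from 0 on the second. By the titles E22A array 1 then lies on the side opposite to CDH1, and 1 of the 16 members was on the E-cadherin side of all 4 arrays, against 8 by the channel labels. None of its members passed over all features, and adjusted over the list alone 0 passed by the titles and 7 by the channel labels. Among the 7, HSP90AB1 stood at only -0.33 and -0.38 on the first arrays as deposited. In E22B the chaperones HSPD1 and HSPA9 stood at 1.25 ± 0.61 and 0.87 ± 0.09, HSPH1 at 1.12 ± 1.37, and the list's median of 0.31 exceeded 99.99% of random lists. Cell cycle and DNA replication genes (38 measured) shifted to the same side by the titles (adjusted p = 9.27e-09, and 0.921 with an estimated correlation) but not by the channel labels (0.200). CHEK1, a checkpoint kinase, stood at 1.08 ± 0.16 in E22B, MAD2L1 at 1.11 ± 0.07 and CCNA2 at 0.45 ± 0.26. By the channel labels the interferon response (21 measured, adjusted p = 0.0135) and the cell cycle inhibitors and p53 targets (22 measured, adjusted p = 0.0234) also shifted to the E-cadherin side, each at 0.869 with an estimated correlation. IFIT3 and IFI44, interferon-induced genes, stood at 1.00 ± 0.42 and 0.66 ± 0.01 in E22B. Of the list of cell cycle inhibitors and p53 targets, PLK2 stood at 1.15 ± 0.54, BTG1 at 1.11 ± 0.06 and CCNG1 at 0.95 ± 0.37. Adjusted over the list alone, 2 interferon genes and 8 of the cell cycle inhibitors and p53 targets passed by the channel labels and 0 by the titles. The 8 include CDKN1B, whose means lay on the side opposite to CDH1. As deposited it stood at -0.04 and -0.18 on the first arrays and at 1.15 and -1.09 on the second. No list was called with fry in any of the 4 readings. The heat shock list was not called in the other readings tried. With the sign of the E22A pair turned, cell cycle genes lay on the E-cadherin side (adjusted p = 0.000275) and ribosomal proteins on the other (0.0217). With channel 2 over channel 1, junction genes and the list of cell cycle inhibitors and p53 targets (0.0404 each) lay on the E-cadherin side. Mesenchymal markers and TGF-beta signalling (0.0203 each) lay on the other. With an estimated correlation these calls were lost too, at 0.941 with the sign turned and 0.758 with channel 2 over channel 1.

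The other 16 lists were not called in either reading, and no member passed over all features. Adjusted over the list alone, 0 members of any list passed by the titles. By the channel labels 4 junction genes (CDH1, CTNNB1, DSP, EPCAM), 5 of keratins and epithelial differentiation, 6 mesenchymal, 3 matrix, 2 protease, 2 bHLH and Id, 2 TGF-beta, 8 growth factor, 1 glycolysis, 2 ribosomal and 4 apoptosis genes passed in this way, and 0 of the remaining lists. The pooled test sees only the mean of each pair, so a gene far from 0 on 1 array of each pair can pass. Among those that passed, EPCAM, SPINT2, LGALS1, SPARC, COL15A1 and MST1R were at 2-fold or more on both first arrays and under 0.5 in size on both second arrays. NRP1 and FAP, under 2-fold on the first arrays, were also under 0.5 on both second arrays. EPCAM changed side within each transfectant after turning. In E22B alone, as a description of 1 sample, the mesenchymal and cytoskeletal markers had a median of -0.24, at percentile 0.02 of random lists by the titles, and junction genes 0.13, at percentile 98.2. In E22A the mesenchymal median was 0.13 by the titles, at percentile 100, and 0.01 by the channel labels, at percentile 65.3. The junction median in E22A was -0.000126 by the titles (percentile 47.0) and -0.02 by the channel labels (percentile 42.9). In the first list ENG, endoglin, stood at -0.90 ± 0.14, while MYL9 (0.48 ± 0.02), FAP (0.43 ± 0.06) and ACTA2 (0.36 ± 0.10) lay on the E-cadherin side. In the second, AFDN stood at 0.34 ± 0.04 and CTNNB1, beta-catenin, at -0.59 ± 0.02, on the side opposite to CDH1. Keratins and epithelial differentiation had a median of 0.08, with SPINT2 at 1.28 ± 1.38 and SPINT1 at 0.44 ± 0.38. TGF-beta and BMP signalling had -0.17 (percentile 0.13), with BMP4 at -1.10 ± 0.15 and SMAD7 at -0.59 ± 0.08. Its E22A median was 0.04 by the titles (percentile 94.2) and -0.03 by the channel labels (percentile 28.5). Extracellular proteases and inhibitors had -0.16 (percentile 0.42; in E22A 15.6 by the titles and 27.7 by the channel labels), although PLAU stood at 1.25 ± 0.05. The bHLH, Id and EMT factors had -0.11, with KLF8 at 1.16 ± 0.05, and the extracellular matrix -0.05, with VCAN at -0.94 ± 0.95. For the bHLH, Id and EMT factors the E22A median was 0.06 by the titles (percentile 96.4) and -0.18 by the channel labels (percentile 0.26).

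The remaining medians in E22B were those of integrins and focal adhesion (-0.01, with ROCK2 at 1.04 ± 0.08), the Wnt pathway (-0.04), growth factors and angiogenesis (-0.01, with VEGFA at 1.20 ± 0.65), hypoxia and glycolysis (0.10, with PKM at -0.80 ± 0.64), ribosomal proteins (0.02), NF-kB and cytokines (0.01) and apoptosis (0.02, with BIRC2 at 0.61 ± 0.20). The markers of cell types not studied had 0.04 for leukocytes and -0.02 for nerve and muscle. In E22A the ribosomal median was -0.10 by the titles (percentile 0.01) and 0.17 by the channel labels (percentile 99.93). The mean and the median over both transfectants differed in sign by the channel labels for the matrix, protease, integrin, growth factor, NF-kB, ribosomal and apoptosis lists. By the titles they did so for the mesenchymal, protease, bHLH, growth factor, hypoxia, leukocyte, and nerve and muscle lists.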

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

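The differences in this part were not tested between biological samples, because each transfectant is 1 sample. The genes below stand out because both E22A arrays lay on one side and both E22B arrays on the other. By the channel labels the differences, E22A minus E22B, were 2.12 for PPP1R14B, 2.01 for ALG8, 1.59 for KYNU, 1.34 for KIAA1958, 1.32 for KISS1R and 1.20 for VPS28. They were -5.29 for DYRK2, -4.51 for POSTN, -3.93 for TENM3-AS1, -3.73 for USP45 and -3.71 for BMPR1B. These 5 draw much of their size from E22B array 2, and without it they were -2.43, -1.97, -0.89, -1.49 and -0.69 in the same order. ALG8 was 1.29 without that array. By the titles they were 3.66 for SPARC, 2.27 for SCN9A and 2.21 for GNG11. For these genes the channel labels give 0.24, -0.07 and 0.50, so these differences rest on the title reading of E22A array 1. They also draw their size from the first array of each transfectant. On the second arrays, as deposited, SPARC stood at -0.25 and -0.11, SCN9A at -0.07 and -0.02 and GNG11 at -0.19 and -0.15.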

How the results depend on the processing

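Of 131 values under alternatives, 61 stayed within the limits used for a match, 65 moved and 5 changed sign. A match meant a count within 1.5 times, or a correlation inside its bootstrap interval. Which features or lists made up a count was not compared, so a matching count can hold other members. With the sign of E22A turned, 2 lists were still called, but ribosomal proteins stood in place of heat shock. The causes were not tested except where a setting's construction gives it. Alternatives combined with the channel-label reading, the channel 2 over channel 1 reading and the turned sign of E22A were chosen after seeing the data. Signal over background is unknown, so its limit could not be set. No paired analysis was possible because the labels give the arrays no replicate number, so the numbers follow record order and only name arrays.

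For E22B the count of 55 became 265 at 1.5-fold, 12 at 3-fold, 1 with limma on separate arrays and 9 without unreliable features. Unreliable means that the arrays of either transfectant differ by over 1 log2 unit after turning, here by the titles. Features whose E22B arrays agree, such as FOS, DSP and TFF1, are thus also left out for their E22A arrays. Leaving out an array gave 218 to 263, since 1 array then meets the rule.

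By the titles the pooled count of 0 became 1 with channel labels. It stayed 0 under every other alternative run, left-out arrays included. The E22A count of 2 became 33 with channel labels or the turned sign, 4 after scaling, 28 at 1.5-fold and 0 at 3-fold, with limma on separate arrays and without unreliable features. It was 181 to 182 with an array left out. E22A against E22B (146) became 475 with the turned sign, 472 at 1.5-fold, 48 at 3-fold, 8 with limma on separate arrays, 34 without unreliable features and 196 to 562 with an array left out. The correlation of -0.0578 changed sign to 0.355 with channel labels and 0.0578 with channel 2 over channel 1, was -0.355 with the turned sign, and ran from -0.394 to 0.273 with an array left out. It was 0.243 without E22B array 1. The agreement of the E22A arrays went from -0.371 to 0.371. The lists called (2) became 4 with channel 2 over channel 1, 0 with an estimated correlation, 0 with fry and 2 to 4 with an array left out. Channel 2 over channel 1 and the turned sign each gave 0 with an estimated correlation and 0 with fry. These lay on both sides with channel 2 over channel 1 (2 and 2), with the turned sign (1 and 1) and without E22A array 2 (1 and 1).

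By the channel labels the pooled count of 1 became 0 without centring or with incomplete features, 5 after scaling, 21 with clones not averaged, 142 at an adjusted p under 0.10, 7 with robust eBayes, 11 with 4 arrays as separate values and 31 without unreliable features. It was 0 to 31 with an array left out, and the 31 came without E22B array 2. The E22A count of 33 became 165 at 1.5-fold, 7 at 3-fold, 0 with limma on separate arrays and 181 to 182 with an array left out. E22A against E22B (130) became 425 at 1.5-fold, 50 at 3-fold, 0 with limma on separate arrays, 63 without unreliable features and 148 to 268 with an array left out. The correlation of 0.355 ran from 0.173 to 0.448 with an array left out. The lists called (3) became 5 with incomplete features, 0 with an estimated correlation, 0 with fry and 3 to 5 with an array left out.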

Other observations

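All tests in this part were chosen after the values had been seen. SPARC, EPCAM and other features were far from 0 on the first array of each transfectant and near 0 on the second. As deposited, EPCAM, an epithelial adhesion molecule, stood at -2.57 and -2.56 on the first arrays and at 0.17 and -0.48 on the second. SPINT2, a protease inhibitor of epithelia, stood at -2.18 and -2.25 against -0.45 and 0.31. MST1R, a receptor kinase, stood at -1.74 and -2.30 against 0.18 and 0.22. On the opposite side LGALS1, galectin-1, stood at 1.89 and 2.53 against 0.25 and 0.12. These genes were chosen after their values were seen, and no theme of the class was tested.

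There were 42 such features, 28 with a gene symbol, at 2-fold or more on both first arrays and under 0.5 on both second arrays, and 13 the other way round, among them HSP90AB1 and CDKN1B. Dye bias of single genes stays open. A comparison of these counts was tried and set aside, because what dye bias predicts for them depends on the dye E22A carried on each array. Uniform compression of the second arrays by the 3.37 times or more that this class needs would leave about 15 values at 2-fold there, and there were 444, against 400 on the first arrays. RNA or a hybridisation shared by the first arrays, which correlated at 0.569 as deposited, cannot be told apart from the rest because no label gives a batch. No biological explanation was tested.

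The E22A arrays ran together as deposited although their titles name opposite dyes. Correct titles with plain dye ratios leave only a dye effect in the sum of the E22A arrays, which argues against them since that sum correlated at -0.173 with E22B array 2 (bootstrap interval -0.243 to -0.105). The channel labels leave neither effect nor dye in the difference of the E22A arrays, and that correlated at 0.243 with the same array (0.177 to 0.298). An exchange of the dyes in the ratio of E22A array 2 would put the dye effect into that difference, which did correlate at 0.568 with the sum of the E22B arrays. It would also leave the sums of both pairs unrelated, which argues against it since they correlated at 0.202 (0.15 to 0.252), and at 0.237 (0.187 to 0.285) with the arrays scaled to 1 SD. By rank that correlation was 0.0160, so it rests on the larger ratios. The tests of the titles and of the exchange take dye and effect as unrelated across features. None of the 3 accounts covers all correlations, the sign of E22A stays open, and RNA shared by the first arrays was not separated from them.

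On E22B array 2, 23 clones stood at 3 or more while both E22A arrays were under 1, all of them above 0, with a median of 4.72. A difference between the RNAs would recur on the dye swap, E22B array 1, where their median was 0.368 (bootstrap interval 0.321 to 0.679) and 1 clone reached 0.5 times its array 2 value or more. Damage to single spots would part the duplicates, whose median difference was 0.0821, although 3 of 22 pairs, those of BMPR1B, USP45 and TOR1AIP1, differed by 1 or more. The clones lay closer together in the clone list than random ones, at a median of 92 clones against 200 (permutation test, one-sided, p = 0.0331), so a local defect of the slide may contribute, if list order follows position, which is not given in the sources used here. TENM3-AS1 is among them, and POSTN and DYRK2, outside the class, also draw their E22B values from this array.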
